A study of Mus musculus with 9 samples.

How the data were processed

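The series measured gene expression by RNA sequencing in mouse bone marrow-derived macrophages cultured for 7 days, in 9 libraries. Groups and replicate numbers came from the sample titles, giving 3 libraries each of untreated wild type, wild type with LPS for 6 h and SRF-KO with LPS for 6 h. In the titles, the libraries called wild type here are named Control. Libraries were made with a stranded TruSeq protocol, per the labels. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic, STAR 2.5.4b, featureCounts and edgeR and the genome build GRCm38, without giving options. The annotation release and the strand setting of the counting are not given in the sources used here. Where genes overlap, or lie antisense to each other, their reads could therefore not be told apart with certainty, and reads of near-identical family members (Gbp, Ifi, H2-Q, Hspa1, Ccl and similar families) can be split or lost.

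The deposited files hold 1 whole-number read count per Ensembl gene and library, per the file headers, without normalization. Each file lists 22524 genes, all with a gene identifier. Symbols were found for 22214 identifiers and not for 310. Coordinates came from GENCODE mouse release 21, which is on GRCm38, for 22291 identifiers. Total counts were 17367182, 17606538 and 15867737 in untreated wild type, 15321839, 17867284 and 19009123 in wild type with LPS, and 21370462, 24912173 and 16987011 in SRF-KO with LPS. Differences in depth were handled by TMM scaling, which assumes that most genes do not change. Since LPS changed a large share of genes, results were also computed with library totals alone.

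The counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the 3 groups (11560 genes), dispersions were estimated robustly, and all 9 libraries entered 1 quasi-likelihood fit (glmQLFit with robust estimation, glmQLFTest) with group as the only term. The contrasts were LPS against untreated in wild type, SRF-KO with LPS against wild type with LPS, and SRF-KO with LPS against untreated wild type. Genes passed at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold. Standard errors of log2 fold changes were calculated from the fold change without shrinkage and the F statistic. A gene with 0 counts in a group got a lower bound of its fold, against 3 counts over the group, and one with 1 to 3 counts got an exact 95% interval of the ratio. These intervals cover counting error only, as PCR copies are not independent molecules. A logarithm of CPM with a prior count of 2 was used for principal components and list tests.

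Gene lists (30 lists, 686 entries) were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move without comparing them with other genes. Adjusted p-values of list tests are over the lists of a comparison. Of 28 testable lists in the LPS comparison 13 passed with the preset correlation and 5 with an estimated one, and in the SRF-KO comparison 14 and 4. Named genes followed a rule also fixed before the data were examined. It took Srf, then the 6 largest rises and 6 largest falls among passing genes with a mean log2 CPM of at least 3, non-overlapping groups and an ordinary symbol, then the 3 members with the smallest p of each list marked as main for a comparison (5 for the cytoskeletal SRF targets), and up to 2 of any other list, with ties by symbol. It covered the first 2 comparisons, and a gene named in 1 of them could have its value given in another. Genes named outside the rule are said to be so. A gene that the rule would name is not reported here. Cxcl11, Mx2, Clec7a, Hbb-b1, Ahsp and Atp6v0a3 were on the lists and are not analysed here.

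The steps were tested on simulated counts with 100 genes changed by each fold. The changed genes had an expected count of at least 20, and as many rose as fell. Most simulated genes were unchanged, so the TMM assumption held by design, whereas most tested genes passed in these data. The shares below therefore do not cover errors of scaling or genes with low counts. For LPS in wild type (10980 genes) 58% of genes changed 1.25-fold and 96% of genes changed 2-fold were recovered, and 6 unchanged genes were called. For SRF-KO against wild type with LPS (10992 genes) the shares were 63% and 100%, with 11 unchanged genes called. The list test with the preset correlation called 0 of 20 unchanged lists in each. Simulated genes varied independently of each other. In these data the estimated correlation was 0.39 for interferon-stimulated and 0.84 for mitochondrially encoded genes. The 0 of 20 therefore does not cover lists whose genes vary together. Shared control libraries were simulated 10 times with no change between groups. Replicates were compared by a chi-square test of counts over genes with at least 20 counts per pair. Alternatives, set before the data were examined, were DESeq2, limma-voom, a test against a minimum fold of 1.5 (glmTreat), DESeq2 size factors or library totals for scaling, no low-count filter, a filter of 5 CPM in at least 3 libraries, fits of only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. Leaving out genes on X and Y was added after the data were seen. No library was left out of the main results.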

Results

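RNA sequencing measured gene expression in bone marrow-derived macrophages (BMDMs), primary macrophages that develop in culture from mouse bone marrow cells. The cells came from C57BL/6 mice and were cultured for 7 days. The 9 libraries formed 3 groups of 3, namely untreated wild-type cells, wild-type cells given lipopolysaccharide (LPS) for 6 h, and SRF knockout (SRF-KO) cells given LPS for 6 h. LPS is a component of the outer membrane of Gram-negative bacteria that macrophages sense through Toll-like receptor 4. SRF, serum response factor, is a transcription factor known for controlling genes of the actin cytoskeleton and immediate-early genes. The design asks what LPS does to gene expression and what part SRF plays in it. No untreated SRF-KO cells were analysed here, so the LPS response within SRF-KO cells could not be measured.

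Each library was described by read counts for 22524 genes. Total counts ranged from 15867737 to 17606538 in untreated wild type, from 15321839 to 19009123 in wild type with LPS and from 16987011 to 24912173 in SRF-KO with LPS. Of all genes, 11560 had enough counts to be tested. Levels are given as CPM, read counts relative to library size, scaled by the trimmed mean of M-values (TMM), as mean ± SD over n = 3 libraries per group, and tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Every pair of replicates differed by more than sampling noise, with chi-square per degree of freedom between 1.75 and 3.95. The spread within groups was nonetheless small, with a common biological coefficient of variation of 3.46%. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. In a principal component analysis the first component held 60.8% of the variance and the second 35.9%. The untreated libraries lay between -93.8 and -92.6 on the first component and the 6 LPS-treated libraries between 41.8 and 51.2. On the second component, wild type with LPS lay between 59.2 and 61.0 and SRF-KO with LPS between -64.6 and -63.4.

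The targeted gene was nearly absent from the libraries labelled SRF-KO. Srf (ENSMUSG00000015605, chromosome 17, 46548329 to 46556175, minus strand, GRCm38) was at 44.3 ± 4.54 CPM in untreated wild type, 57.6 ± 2.17 CPM in wild type with LPS and 1.05 ± 0.438 CPM in SRF-KO with LPS. The raw counts were 810, 975 and 884 in the untreated libraries, 738, 799 and 900 in wild type with LPS, and 34, 24 and 12 in SRF-KO. Between the LPS-treated groups Srf fell by 5.75 on the log2 scale (SE 0.124, adjusted p = 2.85e-32). LPS raised Srf by 0.38 on the log2 scale in wild type (SE 0.0666, adjusted p = 3.03e-06), but with library totals in place of TMM the change was -0.17 (adjusted p = 0.0171). Gene-level counts do not show which exons the remaining reads came from.

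LPS for 6 h raised inflammatory cytokine, chemokine, NF-kB and interferon-stimulated genes in wild-type BMDMs and lowered cell cycle and cholesterol synthesis genes. As lists, the interferon-stimulated and cholesterol synthesis genes did not pass with an estimated correlation (adjusted p = 0.164 and adjusted p = 0.121), and the other 4 did. Il1b, which encodes interleukin-1 beta, rose from 1.89 ± 0.201 to 3377 ± 78.2 CPM (log2 fold change 10.80, SE 0.0727). Nos2, the inducible nitric oxide synthase, rose from 1.31 ± 0.0804 to 1606 ± 50.2 CPM (log2 fold change 10.25, SE 0.0747). Plau, the urokinase plasminogen activator, fell from 531 ± 14.3 to 8.30 ± 0.802 CPM (log2 fold change -6.01, SE 0.0621). Top2a, a DNA topoisomerase of dividing cells, fell from 169.5 ± 10.5 to 24.0 ± 1.52 CPM (log2 fold change -2.82, SE 0.0553).

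In total 9443 of 11560 genes passed the test, 4722 higher and 4721 lower with LPS. Of these, 1805 rose and 2006 fell by at least 2-fold, and 856 rose and 766 fell by at least 4-fold. The CPM ranges of the groups did not overlap for 82.1% of genes, where chance would give 10% for 3 against 3. Among genes picked by size, Il6 (interleukin-6) had 1 count over the 3 untreated libraries and 88.8 ± 5.78 CPM with LPS, a ratio of 5363 (95% counting interval 962 to 211900). Slc1a2, a glutamate transporter, had 0 counts in the untreated libraries and was at least 221-fold higher with LPS, taking 3 counts over the group as the floor. Il1a and Shisa3 rose by 10.23 (SE 0.101) and 10.52 (SE 0.143) on the log2 scale. Nanos1, Rasgrp3, Cdca7, Nav2 and Kitl, which encodes stem cell factor, fell by 6.97, 6.07, 5.94, 5.62 and 5.23 on the log2 scale, and the highest of them, Nav2, was at 2.02 ± 0.367 CPM with LPS. Intervals and floors cover counting error only.

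All 23 tested inflammatory cytokines rose, among them Il1rn, the interleukin-1 receptor antagonist, from 75.7 ± 2.12 to 5196 ± 247 CPM. Their median log2 fold change was 4.06, or 3.80 with the 2 cytokines that had 0 counts in a group at their floor (camera adjusted p = 2.51e-09, and adjusted p = 0.0133 with an estimated correlation). Of 21 chemokines, 19 rose and 2 fell (median log2 fold change 4.22, or 3.42 with 1 member at its floor, adjusted p = 1.04e-06, and adjusted p = 0.0133 with an estimated correlation). Cxcl10, a chemokine for T cells, rose from 46.3 ± 4.69 to 3205 ± 97.2 CPM and Ccl4 from 18.7 ± 0.682 to 879 ± 36.0 CPM. All 24 genes of NF-kB feedback and signalling rose (median 3.05, adjusted p = 1.77e-11, and adjusted p = 0.0358 with an estimated correlation), with Cd40, a co-stimulatory receptor, at 5.91 and Ptgs2, cyclooxygenase-2, at 8.92 on the log2 scale. All 39 interferon-stimulated genes rose (median 2.84, adjusted p = 9.26e-16, but adjusted p = 0.164 with an estimated correlation). The guanylate-binding protein genes Gbp5, Gbp2 and Gbp3 rose by 7.34, 5.85 and 5.58 on the log2 scale, though reads of this family can be shared between near-identical copies. Adjusted over the list alone, each of these 4 lists had the same counts of higher and lower genes as over all genes tested.

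Receptors and adaptors of LPS and related sensing rose in 23 of 28 cases and fell in 4 (median 1.77, adjusted p = 7.13e-06, and adjusted p = 0.0133 with an estimated correlation). Acod1, which makes itaconate, rose from 41.4 ± 3.90 to 8016 ± 32.4 CPM, and Irak3, a brake on Toll-like receptor signalling, from 24.3 ± 0.958 to 431 ± 10.1 CPM. All 19 genes of MHC class I presentation rose (median 1.80, adjusted p = 1.12e-07, but adjusted p = 0.164 with an estimated correlation), including H2-Q6, which has near-identical relatives, and Nlrc5, the class I transactivator, by 2.73 and 2.41. All 19 glycolysis genes rose (median 1.03, adjusted p = 3.75e-07, but adjusted p = 0.173 with an estimated correlation), led by Pfkfb3 at 4.57 and Slc2a1, the glucose transporter GLUT1, at 2.70 on the log2 scale. With library totals 15 of the 19 rose and 3 fell.

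All 36 cell cycle genes fell (median -2.82, adjusted p = 3.28e-12, and adjusted p = 0.0133 with an estimated correlation). The replication helicase genes Mcm3 and Mcm7 fell by 3.12 and 3.65 on the log2 scale. Of 23 cholesterol synthesis genes, 20 fell, 0 rose and 3 did not pass the test (median -0.69, adjusted p = 1.07e-04, but adjusted p = 0.121 with an estimated correlation). Sqle, squalene epoxidase, fell from 52.0 ± 1.45 to 11.3 ± 0.836 CPM, and Dhcr7 and Msmo1 fell by 2.93 and 1.54 on the log2 scale. Adjusted over the list alone, the counts of both lists were the same.

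Immediate-early genes with known SRF control rose in 15 of 22 cases and fell in 4, or 16 and 4 adjusted over the list alone (median 1.35, adjusted p = 0.00474, but adjusted p = 0.173 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, and Ier3 rose by 3.11 and 4.37 on the log2 scale. Of 24 cytoskeletal SRF targets, 15 rose and 6 fell (camera adjusted p = 0.129), and the median of 0.27 turned to -0.27 with library totals (5 risen, 12 fallen). Vasp and Tpm4 rose by 2.76 and 1.84. Actin regulators rose in 27 and fell in 11 of 40 cases (adjusted p = 0.0709), with the median of 0.22 turning to -0.33 with library totals (11 risen, 27 fallen). Fscn1, the actin-bundling protein fascin, rose from 0.551 ± 0.188 to 127 ± 5.07 CPM and Rac2 from 218 ± 12.5 to 864 ± 27.1 CPM. Integrins and adhesion genes rose in 17 and fell in 5 of 26 cases (adjusted p = 0.0188, but adjusted p = 0.257 with an estimated correlation), with the median of 0.53 turning to -0.02 with library totals (12 risen, 10 fallen). Itgal and Src rose by 3.50 and 3.84. Counts adjusted over the list alone were the same for these last 3 lists.

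The remaining lists moved less evenly. Oxidative phosphorylation and TCA cycle genes rose in 23 and fell in 3 of 34 cases (adjusted p = 0.0240, but adjusted p = 0.196 with an estimated correlation), and their median of 0.22 became -0.33 with library totals (1 risen, 26 fallen). Cycs rose by 1.14 and Idh2 fell by 1.49 on the log2 scale. Antioxidant genes under NRF2 rose in 13 and fell in 6 of 20 cases (adjusted p = 0.0696), with Slc7a11, the cystine transporter, up by 6.33 and Gsr by 2.39. Lysosome genes rose in 10 and fell in 15 of 30 cases (adjusted p = 0.300, median -0.12), or in 1 and 27 with library totals (median -0.66), with Lipa and Npc1 down by 2.26 and 1.49 (log2 fold changes -2.26 and -1.49). MHC class II genes rose in 5 and fell in 1 of 12 cases (adjusted p = 0.321), and unfolded protein and heat shock genes in 12 and 7 of 21 cases (adjusted p = 0.336). The medians of both lists, 0.27 and 0.43, became -0.28 and -0.12 with library totals, where 3 rose and 6 fell and where 6 rose and 11 fell. Alternative activation genes rose in 5 and fell in 8 of 14 cases (adjusted p = 0.691). Their median of -0.35 and mean of -0.05 were below 0, whereas the fry test, which weighs each gene by its own spread, pointed upwards. The same held for macrophage identity genes, with 7 risen and 12 fallen of 21 (adjusted p = 0.538, median -0.15, mean -0.06), or 5 and 16 with library totals. Mitochondrially encoded genes rose in 4 of 7 cases and ribosomal protein genes rose in 18 and fell in 1 of 30 cases (15 and 1 adjusted over the list alone). Neither list passed (adjusted p = 0.538 and 0.183), and their medians of 0.14 and 0.09 turned to -0.41 and -0.46 with library totals, where 0 rose and 7 fell and where 0 rose and 28 fell.

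Few markers of other cell types were tested. Of neutrophil and granulocyte markers 5 were tested and 3 rose (adjusted p = 0.188), of B cell markers 4 with 1 risen and 3 fallen (adjusted p = 0.761), and of T and NK cell markers 5 with 2 risen and 3 fallen (adjusted p = 0.761). For T and NK cell markers the median was -0.83 and the mean 0.84, and for B cell markers the median was -0.85 while the fry direction was upwards. Of stromal and endothelial markers 4 were tested and 4 rose (adjusted p = 0.0260, but adjusted p = 0.173 with an estimated correlation). Dendritic cell markers rose in 5 and fell in 1 of 6 cases (adjusted p = 0.0803), osteoclast markers rose in 5 and fell in 3 of 8 (adjusted p = 0.569), and Hdc, the 1 tested mast cell and basophil marker, rose by 7.70. With library totals, neutrophil and granulocyte markers rose in 3 and fell in 2 cases, dendritic cell markers in 4 and 2, and osteoclast markers in 2 and 4. Of 14 erythroid markers, 12 were among the counted genes, and 0 of these had enough counts to be tested.

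The balance of rising and falling genes in this comparison depended on the scaling. TMM factors ranged from 1.18 to 1.19 in untreated libraries and from 0.810 to 0.814 in wild type with LPS, and with library totals alone 2428 genes were higher and 7835 lower, with a median log2 fold change over all genes of -0.57.

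SRF-KO macrophages given LPS had lower interferon-stimulated, MHC class I, actin-related and macrophage genes than wild-type macrophages given LPS, and higher cell cycle, cholesterol synthesis and antioxidant genes. With an estimated correlation the lists of actin regulators, cell cycle and cholesterol synthesis passed. The interferon-stimulated (adjusted p = 0.111), MHC class I (adjusted p = 0.0958), cytoskeletal SRF target (adjusted p = 0.0958), macrophage identity (adjusted p = 0.131) and antioxidant (adjusted p = 0.111) lists did not pass with it. Actb, beta-actin, was at 11387 ± 286 CPM in wild type with LPS and 1404 ± 35.0 CPM in SRF-KO (log2 fold change -3.02, SE 0.0446, adjusted p = 1.71e-37). Mx1, an antiviral GTPase induced by interferon, fell from 1904 ± 37.6 to 78.7 ± 3.85 CPM (log2 fold change -4.59, SE 0.0466), below the 136 ± 6.20 CPM of untreated wild type. Cxcl1, a chemokine for neutrophils, was higher, at 616 ± 21.3 against 19.9 ± 1.11 CPM (log2 fold change 4.95, SE 0.0524). Top2a was at 311 ± 3.52 against 24.0 ± 1.52 CPM (log2 fold change 3.69, SE 0.0538).

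The groups also differed in genes of the Y chromosome. Uty, Ddx3y, Kdm5d and Eif2s3y, which lie between positions 897788 and 1286629 of the Y chromosome, had 942, 2082, 806 and 2161 counts over the wild-type libraries with LPS and 0, 1, 1 and 4 counts over the SRF-KO libraries. Uty was at least 487-fold lower in SRF-KO, with 3 counts over the group as the floor, and Ddx3y was lower by a ratio of 3229 (95% counting interval 578.9 to 127600). The other tested gene placed on Y, Gm47283, named outside the rule, lies apart from these at 90784738 to 90816464. It had 190 and 531 counts and was 0.85 higher in SRF-KO on the log2 scale (SE 0.144, adjusted p = 1.91e-06). In the SRF-KO libraries Gm47283 held 194, 210 and 127 of the 197, 211 and 129 counts assigned to genes placed on Y. Nearly all of these counts thus came from this 1 gene. Whether its reads arose from the Y chromosome or from similar sequence elsewhere was not tested, so they do not show Y expression in SRF-KO. Among X-linked genes chosen after their values were seen, Eif2s3x, Ddx3x, Kdm5c and Kdm6a were 0.80, 0.59, 0.44 and 0.32 higher on the log2 scale in SRF-KO. The genotype groups therefore differed in Y-linked expression as well as in Srf, and this holds beside every gene group of the comparison. Uty, Ddx3y, Kdm5d and Eif2s3y were near 0 in all SRF-KO libraries and expressed in all wild-type libraries. This is the pattern that female SRF-KO and male wild-type cells would give, so sex was confounded with genotype.

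In total 8905 of 11560 genes passed the test, 4521 higher and 4384 lower in SRF-KO. By at least 2-fold, 1605 were higher and 1297 lower, or 1559 and 1257 without genes on X and Y, a count added after the data were seen. Groups did not overlap for 78.0% of genes. Apart from the Y-linked genes, the largest falls among the genes the rule for naming considered were in Fgl2, a fibrinogen-like prothrombinase, from 1189 ± 17.3 to 7.36 ± 1.05 CPM (log2 fold change -7.35, SE 0.0604), and Lipg, endothelial lipase, from 344 ± 15.7 to 2.24 ± 0.109 CPM (log2 fold change -7.26, SE 0.0698). The largest rises were in Ereg, the growth factor epiregulin, from 0.255 ± 0.0923 to 58.4 ± 2.09 CPM, and in Gsta3, Plet1, F3, Aspm and Clec4n. Clec4n, which encodes the fungal receptor Dectin-2, rose from 6.08 ± 0.252 to 213 ± 6.03 CPM (log2 fold change 5.13, SE 0.0681), and F3, tissue factor, from 0.630 ± 0.266 to 23.6 ± 2.42 CPM.

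Of 24 tested cytoskeletal SRF targets, 16 fell, 6 rose and 2 did not pass, with the same counts adjusted over the list alone. Their median was -0.67 (camera adjusted p = 0.0167, but adjusted p = 0.0958 with an estimated correlation), and with library totals 13 fell and 9 rose (median -0.32). Actg1, gamma-actin, fell by 2.34 on the log2 scale to 181 ± 6.38 CPM. The actin-binding proteins Lima1, Cnn2 and Zyx fell by 4.67 (SE 0.102), 5.20 (SE 0.136) and 2.08 (SE 0.0479) on the log2 scale, and Cnn2 was left at 0.817 ± 0.377 CPM. The 6 that rose, named after their values were seen, were Acta2, Cald1, Pdlim7, Myh9, Vcl and Dstn, at 2.20, 3.55, 0.97, 0.47, 0.45 and 0.30 on the log2 scale. Actin regulators fell in 33 and rose in 5 of 40 cases (median -0.55, adjusted p = 7.64e-06, and adjusted p = 0.0296 with an estimated correlation), or in 24 and 11 with library totals (median -0.20). Fscn1, Evl and Coro1a, a coronin that binds actin filaments, fell by 3.41 (SE 0.0614), 2.32 (SE 0.0490) and 1.80 (SE 0.0412).

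Other SRF-related lists were split. Immediate-early genes rose in 12 and fell in 8 of 22 cases (adjusted p = 0.522, median 0.53). Dusp1, Klf6 and Zfp36, which destabilises cytokine messages, fell by 1.77 (SE 0.0382), 1.71 (SE 0.0390) and 1.52 (SE 0.0396) on the log2 scale. Integrins and adhesion genes rose in 11 and fell in 13 of 26 cases (adjusted p = 0.814). Their median of -0.17 and mean of -0.01 were below 0, while the fry direction was upwards, and the median became 0.19 with library totals (13 risen, 11 fallen). Itga9 and Ptk2b fell by 3.81 (SE 0.0830) and 1.75 (SE 0.0407), and Itgax, which encodes CD11c, rose by 2.16 (SE 0.0518). Adjusted over the list alone, these 3 lists of actin regulators, immediate-early genes and integrins gave the same counts.

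**Figure D1:**
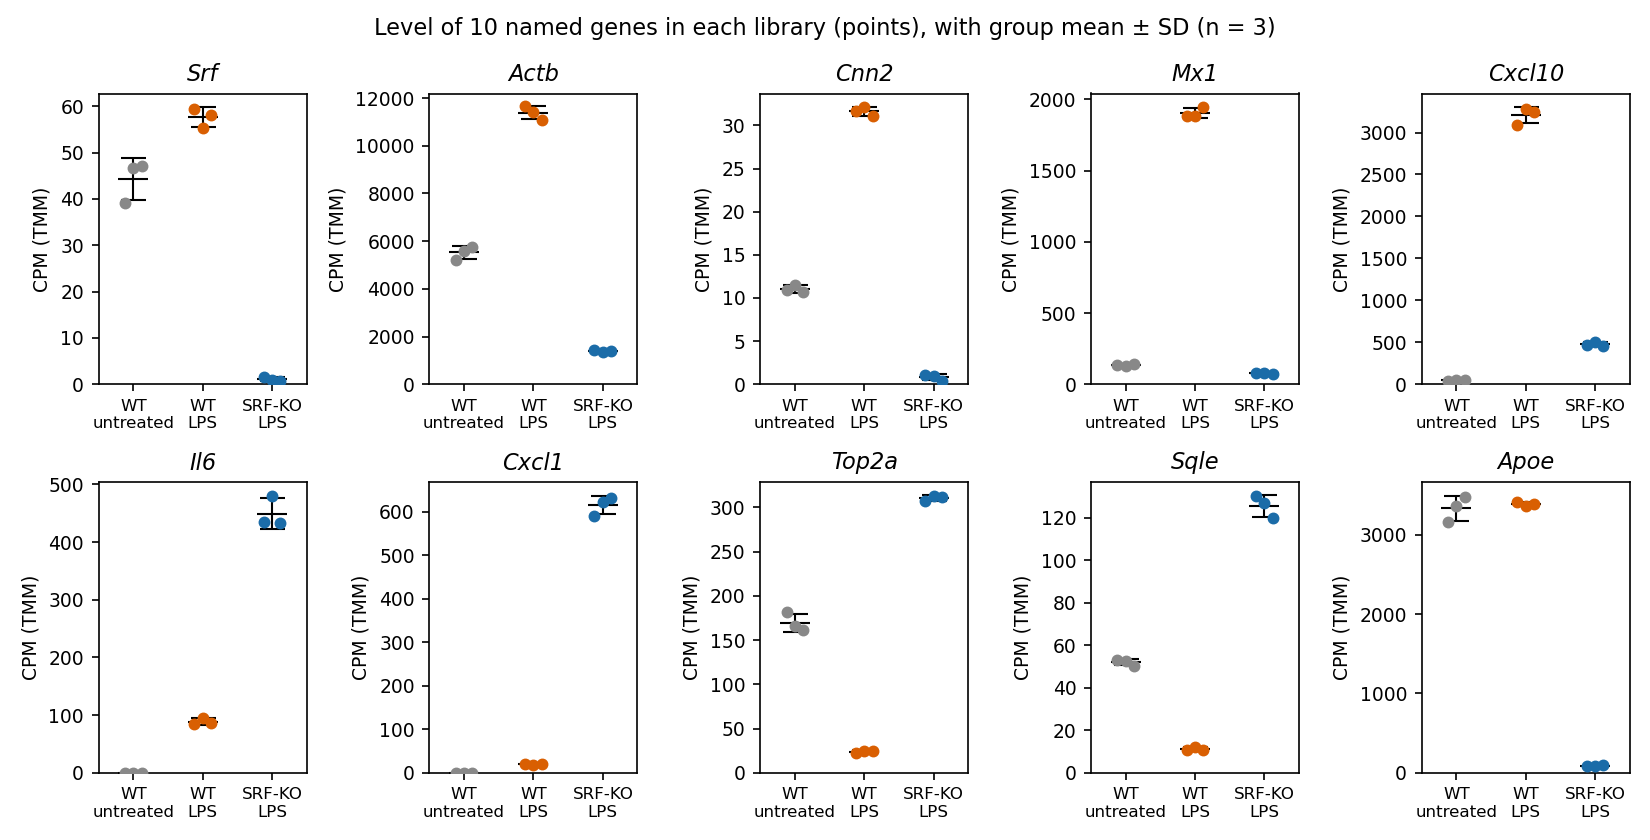
Level of 10 genes in CPM scaled by TMM (vertical axes, linear from 0) in untreated wild type, wild type with LPS and SRF-KO with LPS; points are the 3 libraries of a group, the dash is the mean and bars are ± SD. Srf, Actb, Cnn2, Mx1, Cxcl10 and Apoe were lower in SRF-KO with LPS than in wild type with LPS, at 1.05 against 57.6 CPM for Srf, whereas Il6, Cxcl1, Top2a and Sqle were higher, at 449 against 88.8 CPM for Il6.

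All 39 interferon-stimulated genes were lower in SRF-KO, each by at least 2-fold (median -2.33, adjusted p = 3.52e-18, but adjusted p = 0.111 with an estimated correlation). Ifit2, an interferon-induced inhibitor of viral translation, fell from 2556 ± 56.2 to 187 ± 9.37 CPM (log2 fold change -3.77, SE 0.0441), and Gbp2 from 2478 ± 30.8 to 385 ± 11.6 CPM. All 19 MHC class I genes were also lower (median -1.97, adjusted p = 6.29e-10, but adjusted p = 0.0958 with an estimated correlation). The closely related genes H2-Q6 and H2-Q7, between which reads can be split, fell by 3.44 (SE 0.0490) and 2.95 (SE 0.0457). NF-kB feedback and signalling genes fell in 19 and rose in 5 of 24 cases (median -0.65, adjusted p = 7.84e-04, but adjusted p = 0.181 with an estimated correlation). Tnip3 and Cd40 fell by 2.66 (SE 0.0416) and 2.22 (SE 0.0393), Nos2 by 0.53 (SE 0.0377), while Ptgs2 rose by 2.02 (SE 0.0410). Receptors and adaptors of LPS and related sensing fell in 19 and rose in 5 of 28 cases (median -0.58, adjusted p = 0.00253, but adjusted p = 0.0539 with an estimated correlation), or in 16 and 9 with library totals. Tlr3, a receptor for double-stranded RNA, and Tlr1 fell by 3.36 (SE 0.0550) and 2.46 (SE 0.0445), while Acod1 fell by 0.31 (SE 0.0418) and Irak3 was at 433 ± 2.87 against 431 ± 10.1 CPM (adjusted p = 0.841). Adjusted over the list alone, the counts of these 4 lists were the same.

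Cytokines and chemokines went both ways. Of 23 cytokines, 11 were higher and 10 lower (adjusted p = 0.679, median 0.07), and of 21 chemokines 10 were higher and 10 lower (adjusted p = 0.522, median -0.12, which became 0.24 with library totals), with the same counts adjusted over the list alone. Il6 rose from 88.8 ± 5.78 to 449 ± 26.8 CPM (log2 fold change 2.34, SE 0.0478), Il1b from 3377 ± 78.2 to 7239 ± 75.5 CPM (1.10, SE 0.0384) and Inhba, a subunit of activin A, from 6.82 ± 0.939 to 211 ± 8.06 CPM (4.97, SE 0.0740). Cxcl3 rose from 174 ± 9.03 to 2724 ± 126 CPM. Il15, which sustains NK and T cells, fell from 114 ± 8.76 to 9.86 ± 0.401 CPM (log2 fold change -3.52, SE 0.0664), Cxcl10 from 3205 ± 97.2 to 476 ± 23.4 CPM and Ccl4 from 879 ± 36.0 to 429 ± 16.4 CPM.

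Of 36 cell cycle genes, 34 were higher in SRF-KO and 2 lower (median 3.18, adjusted p = 1.39e-11, and adjusted p = 0.0296 with an estimated correlation). Mki67, the proliferation marker Ki-67, rose from 44.3 ± 3.84 to 507 ± 22.8 CPM, above the 209.9 ± 13.4 CPM of untreated wild type. The 2 lower genes, Mcm6 and Pcna, both of DNA replication and named after their values were seen, were at -0.78 and -0.15 on the log2 scale. Cholesterol synthesis genes rose in 22 and fell in 1 of 23 cases (median 2.03, adjusted p = 2.47e-08, and adjusted p = 0.0430 with an estimated correlation). Sqle rose from 11.3 ± 0.836 to 125 ± 5.23 CPM. Antioxidant genes under NRF2 rose in 17 and fell in 2 of 20 cases (median 0.99, adjusted p = 7.64e-06, but adjusted p = 0.111 with an estimated correlation). Slc7a11 rose from 168 ± 10.9 to 1865 ± 51.0 CPM and Gclm, of glutathione synthesis, from 63.2 ± 1.24 to 319.7 ± 2.35 CPM. Unfolded protein and heat shock genes rose in 14 and fell in 7 of 21 cases (adjusted p = 0.0941), with the chaperone gene Pdia4 up by 1.76 on the log2 scale. Adjusted over the list alone, the counts of these 4 lists were the same.

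**Figure D2:**
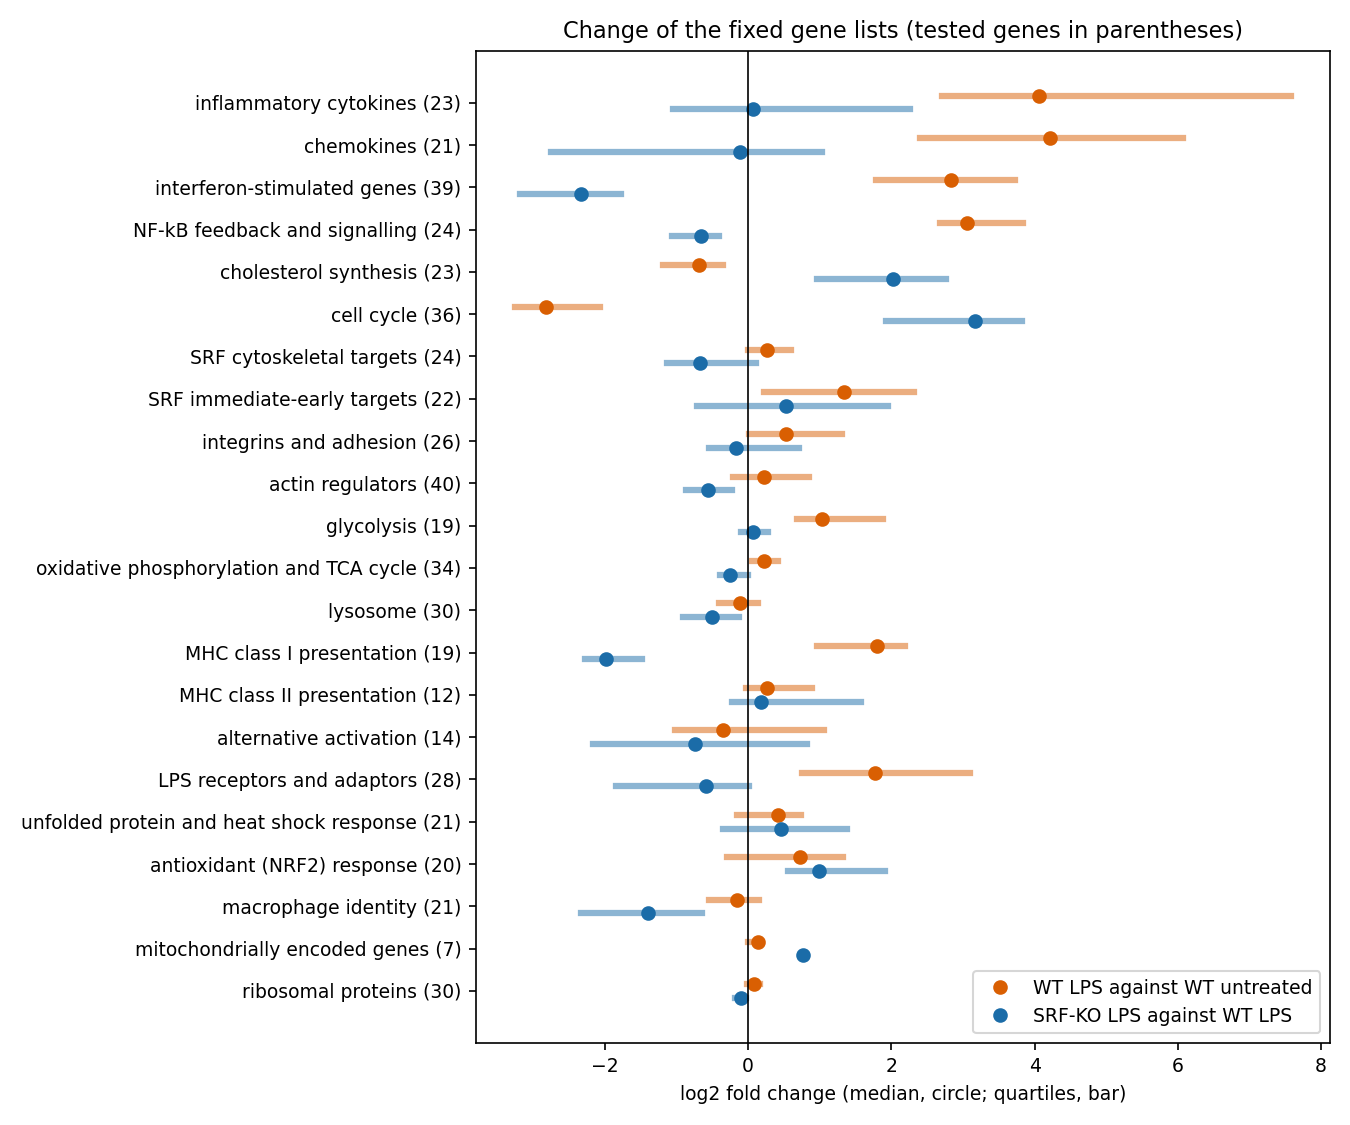
Median log2 fold change (circles) with quartiles (bars) of the tested genes of 22 lists, for LPS in wild type (orange) and for SRF-KO with LPS against wild type with LPS (blue), with 3 libraries per group. Interferon-stimulated genes had medians of 2.84 and -2.33 and cell cycle genes of -2.82 and 3.18; with library totals, medians turned sign for SRF cytoskeletal, integrin, actin regulator, oxidative phosphorylation, MHC class II, unfolded protein, mitochondrial and ribosomal lists under LPS and for chemokine, integrin, oxidative phosphorylation and ribosomal lists in SRF-KO.

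Macrophage identity genes fell in 17 and rose in 4 of 21 cases (median -1.39, adjusted p = 6.89e-05, but adjusted p = 0.131 with an estimated correlation). Apoe, apolipoprotein E, fell from 3390.2 ± 25.7 to 90.0 ± 4.69 CPM (log2 fold change -5.24, SE 0.0502) and Fcgr1, the high-affinity IgG receptor, to 84.2 ± 5.04 CPM (log2 fold change -4.46, SE 0.0457). The 4 that rose, named after their values were seen, were Csf1r, Lyz2, Cebpa and Ctsk, at 0.36, 0.46, 1.30 and 4.47 on the log2 scale. Lysosome genes fell in 23 and rose in 5 of 30 cases (median -0.50, adjusted p = 5.70e-04, and adjusted p = 0.0430 with an estimated correlation), or in 16 and 11 with library totals (median -0.14), with Ctsb, cathepsin B, at 4062 ± 40.8 against 10811 ± 259.8 CPM and Npc2 down by 1.26 (log2 fold change -1.26). Osteoclast markers rose in 7 and fell in 1 of 8 cases (median 1.51, adjusted p = 0.0227, but adjusted p = 0.111 with an estimated correlation). Dcstamp, needed for fusion of osteoclasts, rose from 1.94 ± 0.0697 to 27.3 ± 2.24 CPM, and Tnfrsf11a, the RANK receptor, fell from 279 ± 7.22 to 44.2 ± 1.55 CPM. Alternative activation genes fell in 8 and rose in 4 of 14 cases, or 8 and 5 adjusted over the list alone and 8 and 6 with library totals (adjusted p = 0.190), with Il4ra and Folr2 down from 1568 ± 51.4 to 304 ± 6.72 CPM and from 344 ± 11.9 to 71.8 ± 2.21 CPM. MHC class II genes rose in 6 and fell in 4 of 12 cases (adjusted p = 0.596), or in 8 and 1 with library totals, with Cd80 up by 2.85 and Cd86 at -1.93. For the other lists of this paragraph the counts adjusted over the list alone were the same.

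Glycolysis genes rose in 9 and fell in 6 of 19 cases (adjusted p = 0.522), with a median of 0.07, a mean of -0.07 and a downward fry direction. With library totals, 17 rose and 2 fell (median 0.42). Pfkfb3 fell by 1.67 on the log2 scale. Oxidative phosphorylation and TCA cycle genes fell in 23 and rose in 6 of 34 cases (adjusted p = 0.0215, but adjusted p = 0.219 with an estimated correlation), and their median of -0.25 became 0.10 with library totals (4 fallen, 19 risen). The 7 tested mitochondrially encoded genes rose (median 0.77, adjusted p = 0.0209, but adjusted p = 0.440 with an estimated correlation). Their share of all counts was 0.815% ± 0.0669 in wild type with LPS and 1.46% ± 0.105 in SRF-KO. Ribosomal protein genes fell in 16 and rose in 4 of 30 cases (adjusted p = 0.179), and their median of -0.09 became 0.26 with library totals (0 fallen, 26 risen). Among markers of other cells, 5 neutrophil and granulocyte markers were tested with 3 higher and 1 lower (adjusted p = 0.297), 4 of B cells with 0 higher and 3 lower (adjusted p = 0.142), 5 of T and NK cells with 2 higher and 2 lower (adjusted p = 0.908, median 0.55, mean -1.15), 4 of stroma and endothelium with 1 higher and 3 lower (adjusted p = 0.196) and 6 of dendritic cells with 1 higher and 3 lower (adjusted p = 0.297). The median of the dendritic cell markers, -0.34, was 0.00 with library totals (2 higher, 2 lower). Hdc, for mast cells and basophils, fell by 0.76, and 0 erythroid markers were tested. With library totals in place of TMM, 7059 genes were higher and 2434 lower in SRF-KO, and the median over all genes was 0.37.

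Genes that LPS had changed in wild type were compared with their level in SRF-KO. Of the 856 genes that LPS raised at least 4-fold, 536 were lower in SRF-KO than in wild type with LPS, 243 were higher and 77 did not pass, and 733 of the 856 were still higher than in untreated wild type. By at least 2-fold, 387 were lower and 142 higher. Of the 766 genes that LPS lowered at least 4-fold, 557 were higher in SRF-KO, 69 were lower and 140 did not pass. Over all genes, 2966 were raised by LPS and lower in SRF-KO, 2829 lowered by LPS and higher in SRF-KO, 1012 raised and higher, and 798 lowered and lower. Lists drawn independently would share 1791, 1846, 1847 and 1790 genes. Because both comparisons used the wild-type libraries with LPS, with opposite sign, chance values of these libraries also push them apart. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of -0.378 and a covariance of -0.743. In 10 simulations of unchanged groups sharing these libraries the mean covariance was -0.0231, the mean correlation -0.526, and edgeR's test gave 0 shared calls, against a mean of 111.7 genes, at most 126, shared at an unadjusted p below 0.05. The 3 shared libraries cannot be divided into groups of at least 2 each, so part of the excess of opposite changes may come from sharing them.

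**Figure D3:**
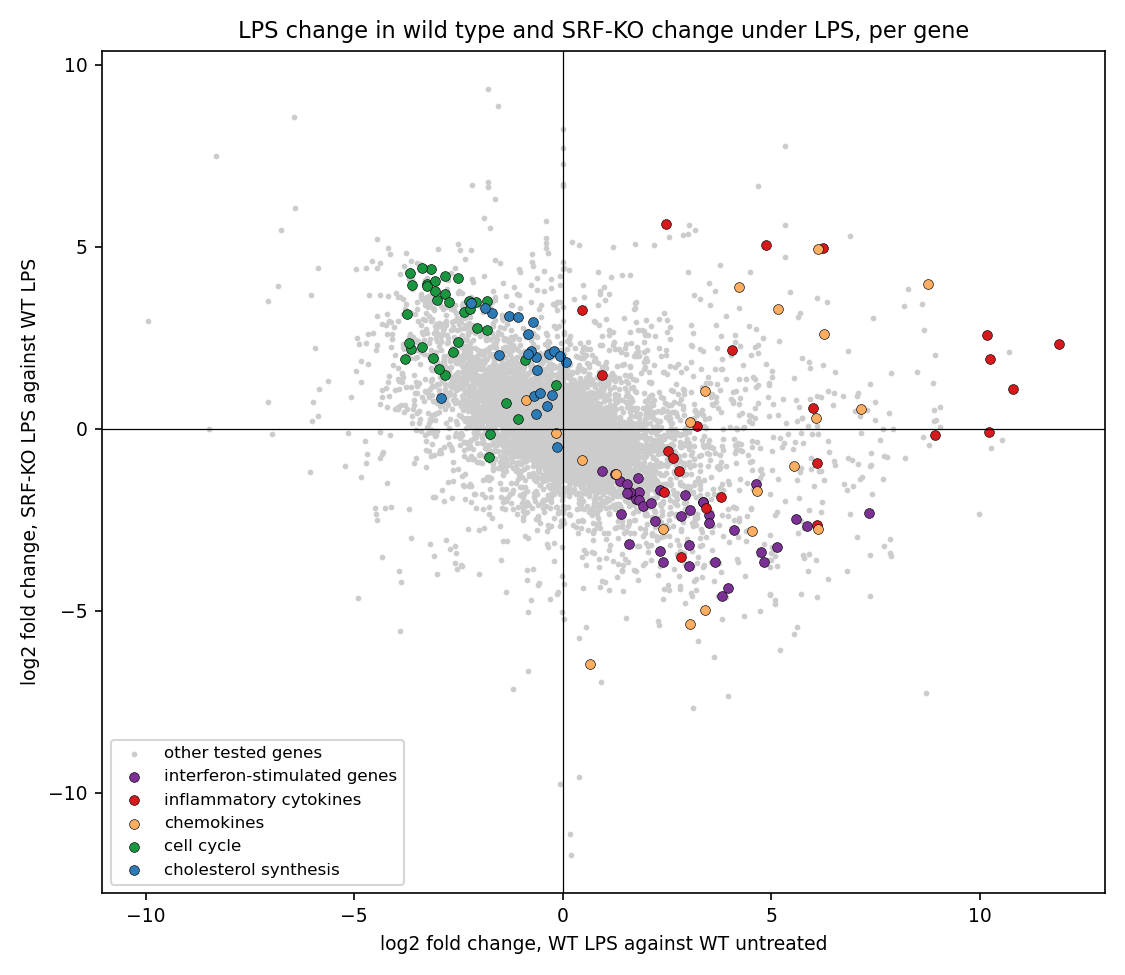
Log2 fold change of each tested gene for LPS in wild type (horizontal axis) and for SRF-KO with LPS against wild type with LPS (vertical axis), from 3 libraries per group, with 5 gene lists in colour. The 39 interferon-stimulated genes lie at the lower right, 34 of 36 cell cycle genes at the upper left, and cytokines and chemokines on both sides of 0 on the vertical axis; both axes share the wild-type libraries with LPS.

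Against untreated wild type, SRF-KO cells given LPS had higher cytokine, NF-kB and antioxidant genes and lower lysosome and macrophage genes, while interferon-stimulated genes were divided. With an estimated correlation the cytokine and lysosome lists passed, and the NF-kB (adjusted p = 0.0694), antioxidant (adjusted p = 0.0820) and macrophage identity (adjusted p = 0.157) lists did not. This comparison joins genotype and LPS, and Y-linked expression differed here too, with Uty at least 427-fold lower in SRF-KO. Cytokines were higher in 21 and lower in 1 of 23 cases (adjusted p = 3.20e-09, and adjusted p = 0.0252 with an estimated correlation). NF-kB genes were higher in 22 of 24 cases (adjusted p = 2.69e-10, but adjusted p = 0.0694 with an estimated correlation). Of 39 interferon-stimulated genes, 17 were higher and 16 lower (adjusted p = 0.307, median 0.01, which became -0.18 with library totals, where 17 were higher and 22 lower). Mx1 and Ifit2 were 0.78 and 0.75 lower (log2 fold changes -0.78 and -0.75), whereas Gbp5 and Cxcl10 were 5.01 and 3.36 higher. Antioxidant genes were higher in 19 of 20 cases (median 1.74, adjusted p = 1.14e-07, but adjusted p = 0.0820 with an estimated correlation), and lysosome genes lower in 25 of 30, or 26 adjusted over the list alone (median -0.62, adjusted p = 7.74e-07, and adjusted p = 0.0252 with an estimated correlation). Cell cycle genes were higher in 22 and lower in 14 of 36 cases (adjusted p = 0.525), with a downward fry direction against a median of 0.69 and a mean of 0.13. Macrophage identity genes were lower in 16 and higher in 5 of 21 cases (adjusted p = 2.51e-04, but adjusted p = 0.157 with an estimated correlation), with Apoe at -5.21 on the log2 scale. Of neutrophil and granulocyte markers 4 of 5 were higher and 1 lower (median 4.62, adjusted p = 0.0256, but adjusted p = 0.126 with an estimated correlation), with Mmp8 and S100a8 at 72.8 ± 5.65 and 16.1 ± 0.332 CPM in SRF-KO. The 7 mitochondrially encoded genes were higher (median 0.93, adjusted p = 0.0161, but adjusted p = 0.435 with an estimated correlation), and their share of all counts was 1.46% ± 0.105 against 1.05% ± 0.0624 in untreated wild type. Other lists passed camera with the preset correlation and not with an estimated one. Glycolysis genes were higher in 18 of 19 cases (adjusted p = 7.74e-07, but adjusted p = 0.167 with an estimated correlation), immediate-early genes in 19 of 22 (adjusted p = 2.04e-05, but adjusted p = 0.0820 with an estimated correlation) and cholesterol synthesis genes in 20 of 23 (adjusted p = 8.52e-05, but adjusted p = 0.0820 with an estimated correlation). Unfolded protein and heat shock genes were higher in 17 of 21 cases (adjusted p = 2.51e-04, but adjusted p = 0.0820 with an estimated correlation), chemokines in 13 of 21 with 6 lower (adjusted p = 0.00943, but adjusted p = 0.0820 with an estimated correlation) and integrins in 17 of 26 with 8 lower (adjusted p = 0.0372, but adjusted p = 0.340 with an estimated correlation). Actin regulators were lower in 25 and higher in 12 of 40 cases, or in 28 and 6 with library totals (adjusted p = 0.0251, but adjusted p = 0.0956 with an estimated correlation). Except for the lysosome list, these counts were the same adjusted over the list alone. In total 9192 genes passed, 4554 higher and 4638 lower, of which 1550 and 1499 by at least 2-fold. With library totals the split was 3448 higher and 6042 lower, with a median over all genes of -0.20.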

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

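Leaving out genes on X and Y was chosen only after the result was seen, and every other alternative was set before. Without them, 8636 genes were called for SRF-KO against wild type with LPS, 2816 of them changed at least 2-fold. DESeq2, limma-voom, DESeq2 size factors in edgeR, other low-count filters, fits of the compared libraries alone and the replicate block kept every count of called genes within 1.5 times of its main value, and limma-voom kept 9381, 8825 and 9154 calls of the 3 comparisons in the same direction (DESeq2 9112, 8496 and 8735). Requiring a fold above 1.5 with glmTreat, which by construction calls fewer genes, gave 4994 genes for LPS in wild type (2443 higher, 2551 lower), 3896 for SRF-KO against wild type with LPS (2089 higher, 1807 lower), 4211 for SRF-KO with LPS against untreated wild type (2164 higher, 2047 lower) and 2246 genes changed in opposite directions by LPS and in SRF-KO. Srf, at 0.38, did not pass it for LPS (adjusted p = 1). With library totals, LPS gave 2428 higher and 7835 lower genes (2-fold: 1172 and 3631) and SRF-KO against wild type with LPS 7059 and 2434 (2-fold higher: 2474). For LPS, Srf turned to -0.17, mt-Nd5 to -0.26, mt-Co1 to -0.33 and Rps9 to -0.00771. These shifts follow from leaving out the TMM factors, and which scaling is nearer to the RNA content of the cells was not tested. Of the main calls, 1301 for LPS and 569 for SRF-KO against wild type with LPS passed in the opposite direction with library totals. List tests gave 5 and 4 lists with an estimated correlation and 27 and 24 with fry, which asks another question, against 13 and 14 in the main test.

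Leaving out each library in turn changed the sign of 0 edgeR calls and lost between 294 and 499 calls. With the replicate number as a block there were 9467, 8919 and 9231 calls and 5813 genes changed in opposite directions, and the block changed no count by over 1.5 times. Same-numbered libraries correlated, over 8498 genes, at -0.10, 0.03 and 0.09 between untreated and LPS-treated wild type, at -0.14, 0.00 and 0.14 between untreated wild type and SRF-KO, and at 0.09, 0.31 and 0.06 between the LPS-treated groups. Not every library correlated best with its own number, and the libraries were not treated as paired. Apart from these results, 2417 values of named genes and lists kept their side of the threshold under an alternative, 32 passed only in the alternative and 32 only in the main test. Among the 2417, values that passed in both settings kept their direction, while some that passed in neither changed it. Depth limits genes near 0 counts, such as Y-linked genes in SRF-KO, to bounds or wide intervals.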

Other observations

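All tests in this part were chosen after the results were seen, except the regrouping of libraries and the results of the gene lists, which were planned. Genes were grouped by the start of their symbol into 190 families, and families were tested for members at least 4-fold changed in SRF-KO with LPS against wild type with LPS (one-sided Fisher's exact test against the 477 lower and 630 higher of 11560 genes). Of 17 tested Ifi genes 11 were lower (adjusted p = 1.98e-09) and of 8 Gbp genes 7 (adjusted p = 2.86e-07), families of interferon-induced proteins that overlap the list of interferon-stimulated genes. Of 10 Toll-like receptor genes 4 were lower (adjusted p = 0.0390), with Tlr9, a receptor for unmethylated CpG DNA, at 2.93 against 66.1 CPM. Of 31 kinesin genes (Kif) 11 were higher (adjusted p = 4.55e-05), with 2 lower. Of 8 Cxcl chemokine genes 4 were higher (adjusted p = 0.0390), with Cxcl2 at 1337 against 136.5 CPM, and 2 were lower (adjusted p = 0.766), so the family went both ways. Tlr9 and Cxcl2 are examples given outside the rule for naming. Genes of a family are not independent of each other, and reads can be shared between close relatives.

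Other groupings of the 6 libraries of each comparison into 3 and 3 are too few for a share under 0.05, since there are 10 with the real one. The real grouping, 1 of 10, called 9443, 8905 and 9192 genes, and the highest of the others called 0 with edgeR, or 75, 113 and 89 genes at an unadjusted p below 0.05. Each of the others mixed libraries of both groups, whose difference then counted as spread. Few calls were therefore bound to follow, and the contrast decides nothing about calls made by chance.

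The SRF-KO difference covered much of the genome, and Y-linked genes differed with it. Only 363 tested genes lay on X and Y, so they could not make up most of the 2902 genes changed at least 2-fold. Their share was 2.96%, against 3.14% of tested genes, so they changed no more often than other genes. This does not weigh on sex as a cause, since effects of X and Y genes on genes elsewhere were not tested. Only 109 tested genes lay within 10 Mb of Srf, so their share of the genes changed at least 2-fold, 1.07%, was bound to be small and decides nothing. Of those near Srf, 28.4% changed against 25.1% of all (Fisher's exact test over genes, two-sided p = 0.437), so no excess near the locus was detected. Effects of foreign strain DNA around the locus on genes elsewhere were not tested. Effects of sex or of separate preparation of the animals may contribute, as 0 SRF-KO libraries had Ddx3y in the wild-type range. Such effects cannot be told apart from genotype, because no library of one genotype shares the sex signal of the other. Sex-dependent and genotype-dependent effects both stay open.

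Interferon-stimulated genes were lower in SRF-KO while several cytokines were higher. Weaker stimulation would bring LPS-changed genes closer to untreated levels, and of those changed at least 4-fold 45.2% of the raised were at least 2-fold lower in SRF-KO and 62.9% of the lowered at least 2-fold higher, so it may contribute. But 16.6% of the raised were at least 2-fold higher and 5.35% of the lowered at least 2-fold lower. This argues against weaker stimulation as the whole cause only if SRF-KO cells start from the levels of untreated wild type. No untreated SRF-KO library was analysed to show that. An earlier or later phase of the response may account for it and stays open, since the series has 1 LPS time. A lower level before LPS may also contribute, but of 39 interferon-stimulated genes 16 were below and 17 above untreated wild type in SRF-KO with LPS (median 0.01, with 3 lower and 12 higher by at least 2-fold), and only untreated SRF-KO cells could decide it.

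Macrophage identity genes were mostly lower in SRF-KO. A lower share of macrophages would lower them together, and 17 were lower, but 4 were higher, which decides nothing because osteoclast-like cells can express part of these genes, so it stays open. Neutrophils, B cells, T cells, erythroid or stromal cells would bring their abundant transcripts. Of 10 such markers, picked after the data were seen, the highest was Camp, a neutrophil marker, at 2.70 CPM in SRF-KO. But Mmp8 and S100a8, also on the neutrophil list, were at 72.8 and 16.1 CPM, and 3 of 5 tested markers of that list were higher and 1 lower, so neutrophils stay open. The highest picked marker of the other types, Cd79a, was at 0.0424 CPM, so the picked markers of those types were nearly absent. Of the tested list markers, 0 of 4 for B cells were higher and 3 lower. For T and NK cells 2 of 5 were higher and 2 lower, and for stroma and endothelium 1 of 4 and 3. Because the picked markers were chosen after the data were seen, their low levels do not exclude those types. Osteoclast markers rose in 7 of 8 cases (median 1.51, adjusted p = 0.0227, but adjusted p = 0.111 with an estimated correlation). The 1 that fell was Tnfrsf11a, the RANK receptor. Ctsk, 1 of the 4 higher identity genes, is also a typical osteoclast gene. A shift of the culture towards osteoclast-like cells, which is itself a lower share of macrophages, a change of state within the macrophages, and sex or preparation may each contribute, were not tested and stay open.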
